A study of Solanum virginianum with 2 samples.

How the data were processed

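Per the labels, total RNA was extracted from eggplant pistils with a Norgen Biotek kit, the small RNA library was made with the Illumina TruSeq small RNA kit, and the degradome library followed the method of German and colleagues. That method captures the 5′ ends of uncapped, polyadenylated RNA, such as cleavage products. Each library was a mixture of S-morph and L-morph pistils. The labels name days 1 to 3 and 3 to 6 for both libraries, while the extraction protocol in the labels adds phase 5 for the degradome. Which programs trimmed and named the small RNAs, predicted the targets and set the degradome categories, and which genome build was used, is not given in the sources used here. Transcripts are named as in the deposited table, where the identifiers begin with Sme2.5. Positions are nucleotides along the transcript, and genome coordinates were not used here. Microarray measurements of the study were not analysed here.

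The small RNA table, per the file headers, held read counts per distinct sequence, and the deposited values were whole numbers from 1 to 32546. The names give the plant of the closest known miRNA with codes for added, removed or substituted bases, or begin with PC where there was none. The table is a list of named sequences and not the whole library, so shares are shares of the listed reads. In the degradome table the authors gave an alignment score per pair, from 0 to 4, where lower means fewer mismatches. The authors also gave raw degradome read counts at the cleavage position for each detected pair. The deposited normalized reads, a signal value, never exceeded the raw reads and were lower in 360 of 1010 detected pairs. They were read as raw reads divided over the places they match, which the header does not spell out. The deposited TPB column, also a signal value, was 105.324 for each normalized read in every detected pair; if TPB scales to 1e+09 reads, which the header does not spell out, the library held 9494500 reads. The authors' p-value per pair was taken as deposited and treated as unadjusted. The authors' category from 0 to 4 was taken as deposited. All 510 pairs of category 4 had 1 raw read and 0 pairs of categories 0 to 3 did. The cleavage position lay 9 nt before the end of the alignment in 923 pairs, 8 nt in 37 and 10 nt in 50. Among undetected pairs 17 were listed at position 0.

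Before the data were examined, the textbook target words, 9 gene lists, the tests, most alternatives and the rule for named items were fixed. The words were used for 32 families, fewer than they had been fixed for, and miR2111 (3 reads) was left out. The search patterns that carry those words over to gene symbols, such as FBX6 for the F-box target of miR394, were written after the symbols had been seen. The homeobox word of miR166 also takes in members outside class III. Symbols and annotations were used as deposited, and they disagree for some transcripts. A family is the miR number of the name, and related names were joined. A site is 1 family on 1 transcript position, which gave 859 sites, 574 of them with an annotation or symbol. For a site hit by several names, the lowest category and then the lowest authors' p was kept. Transcripts were counted 1 time in the tests of categories and lists.

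Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The first base was tested with an exact two-sided binomial test against 0.25, textbook targets with one-sided Fisher's exact tests, and categories and lists with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 27 families or 7 lists tested and a limit of 0.05. With all predicted transcripts as background, all 9 gene lists were tested and adjusted together. The relation of reads and detected transcripts used 100000 permutations on log values, with a pseudocount of 1 for transcripts. Tests on simulated data recovered 100 of 100 planted families in the textbook target test (574 sites), with 1 of 540 called after shuffling. The planted families had several sites, and for miR396 more of them carried the word than the observed 9 of 100. Families with few annotated sites, such as miR162 and miR168 with 1 each, were not planted, so power was not measured for them. The 540 include families whose word matches 0 sites, such as miR397 and miR408, which cannot be called. Shuffling also broke up neighbouring sites. The category test recovered 20 of 20 planted differences (666 transcripts) with 0 of 20 after shuffling. The list test recovered 20 of 20 planted lists, where every disease resistance transcript was set to category 0. The observed list had 5 of 13 in category 0 or 1, so this does not measure power at the observed size. After shuffling 2 of 180 lists were called, including in the 180 those without a detected transcript, which cannot be called. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

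Named items were the 10 most abundant small RNAs, for each family the textbook target with the most reads at its site, the 10 category 0 sites with most reads, up to 3 transcripts per list by category and then reads, and the 5 small RNAs with most target transcripts. Further families and transcripts named outside this rule, such as ATHB-14 and HOX10, were chosen after their values were seen. Alternatives covered a minimum of 10 reads, distinct sequences, removal of the most abundant families, the authors' p at most 0.05, alignment scores of 2.5 or less, categories 0 to 2, and 1 vote per annotation. Alternatives chosen after seeing the data left out repetitive small RNAs (distinct 3 nt words at most 0.5 of all words in the sequence), names known to match ribosomal or transfer RNA, sequences named PC, or sites whose reads match more than 1 place, or used all predicted transcripts as background, and 1 compared detection of textbook targets with other predicted transcripts within each family. With 1 mixed library of each kind, morphs and phases could not be compared.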

Results

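Small RNAs and RNA cleavage products were sequenced from pistils of the long purple eggplant line 'B3-3', which bears flowers of both style types on the same plant. Short-styled flowers (S-morph) have long stamens, and long-styled flowers (L-morph) have short stamens. The 2 libraries, 1 of small RNAs and 1 of RNA 5′ ends (degradome, also called parallel analysis of RNA ends), each held a mixture of both morphs, so the morphs were not compared. The tissue came from flower buds at 1 to 3 and 3 to 6 days after budding according to the sample labels, whereas the extraction protocol in the labels gives 6 pooled samples from phases 1, 2 and 5 for the degradome, phase 5 being days 13 to 15. The organism field of the labels reads Solanum virginianum and the series title reads Solanum melongena. The small RNA table listed 686 distinct sequences with 135737 reads in all. The degradome table listed 18764 predicted pairs of a small RNA and a transcript, and its TPB column, if scaled to 1e+09 reads, implied a library of 9494500 reads. Neither library had a replicate, so intervals are exact Clopper-Pearson 95% intervals that cover counting error only, and p-values describe these libraries and not the plants.

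The first question was which miRNA families the pistils contained, and in what amounts. The miR482 family, known to target disease resistance genes of the nucleotide-binding site and leucine-rich repeat type (NBS-LRR), held 36554 reads or 26.9% of the listed reads (26.7 to 27.2%). The miR166 family, which targets homeodomain-leucine zipper genes of organ polarity, held 21147 reads (15.6%). The miR159 family, whose textbook targets are GAMYB genes of anther and seed development, held 10812 reads (7.97%), and its relative miR319, which targets TCP genes of leaf and petal growth, held 3220 reads (2.37%). The solanaceous miR5300 held 6421 reads (4.73%). The miR2911, miR2916, miR1310 and miR6300 names, which are known to match ribosomal or transfer RNA, held 10.1%, 6.81%, 2.58% and 2.25% of the reads. Other conserved families had 2074 reads for miR171, 2024 for miR160, 1716 for miR172, 1366 for miR167, 1170 for miR396, 501 for miR164 and 208 for miR156. The auxin receptor regulator miR393 had 20 reads.

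**Figure D1:**
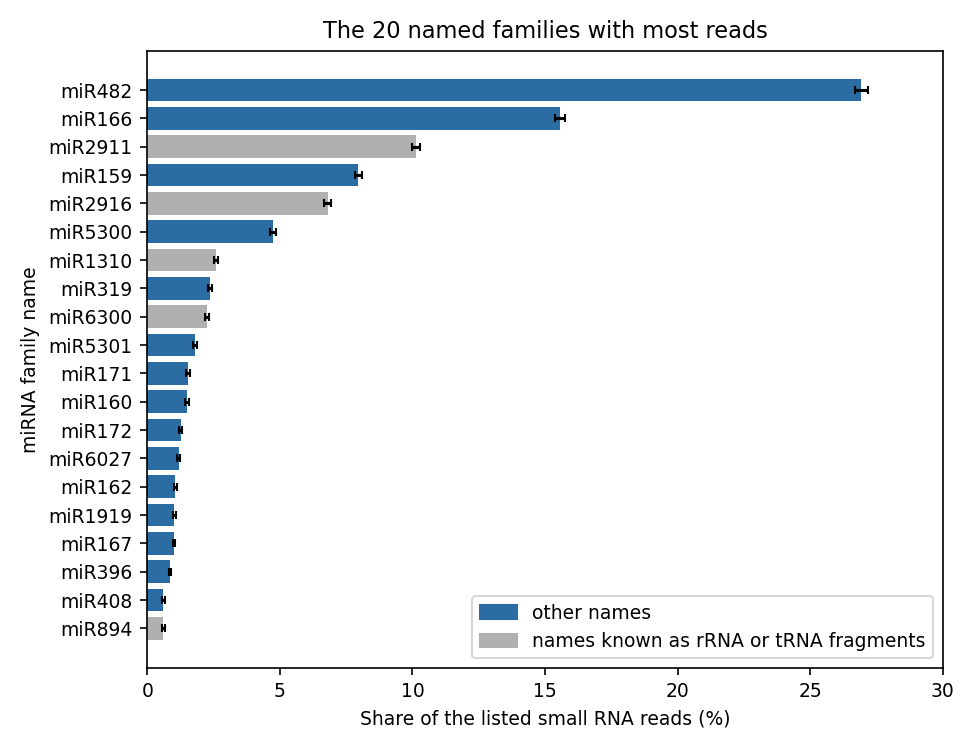
Share of the listed small RNA reads (%, horizontal axis) for the 20 named families with most reads, with exact 95% intervals as error bars and grey bars for names known to match ribosomal or transfer RNA. The miR482 bar reaches 26.9% and the miR166 bar 15.6%, and miR2911 is the highest of the grey bars at 10.1%.

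A few sequences made up most of the small RNA reads. The 10 most abundant sequences held 65.9% of all reads (65.7 to 66.2%). A 22 nt miR482b (UCUUGCCUGCACCGCCCAUGCC) alone had 32546 reads, which was 24.0% of the total (23.8 to 24.2%). The next were a miR166a variant (UCUCGGACCAGGCUUCAUUCC, 12244 reads, 9.02%) and miR159 (UUUGGAUUGAAGGGAGCUCUA, 10048 reads, 7.40%). A miR5300 variant (UUCCCAGUCCAGGCAUUCCAAC) had 6421 reads, and a pair of further miR166a forms had 4169 reads (UCGGACCAGGCUUCAUUCCCC) and 3110 reads (UCGGACCAGGCUUCAUUCCUC). The remaining 4 of the 10 carried the names miR2911 (6495 and 5202 reads) and miR2916 (5998 and 3242 reads). At the other end, 154 sequences had 1 read and 478 had under 10. The 349 sequences without a known family, whose names begin with PC, held 4581 reads (3.37%).

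Length separated the known families from the sequences without one. Among distinct sequences, 24 nt was the most frequent length, with 268 of 686 (39.1%, 35.4 to 42.8%), followed by 21 nt with 182 (26.5%) and 22 nt with 74 (10.8%). Of the 349 sequences without a known family, 222 were 24 nt long (63.6%, 58.3 to 68.7%), whereas 136 of the 337 named sequences were 21 nt long (40.4%, 35.1 to 45.8%) and 46 were 24 nt long. Counted by reads the order changed: 22 nt held 41.6%, 21 nt held 36.8% and 24 nt held 4.58%, with miR482b supplying more than any other sequence of the 22 nt class. Of the 182 sequences of 21 nt, 91 began with U (50.0%, 42.5 to 57.5%), above a share of 0.25 for equal bases (exact two-sided binomial test, p = 4.57e-13), and these carried 89.4% of the 21 nt reads. Related sequences of a family are not independent in this test.

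**Figure D2:**
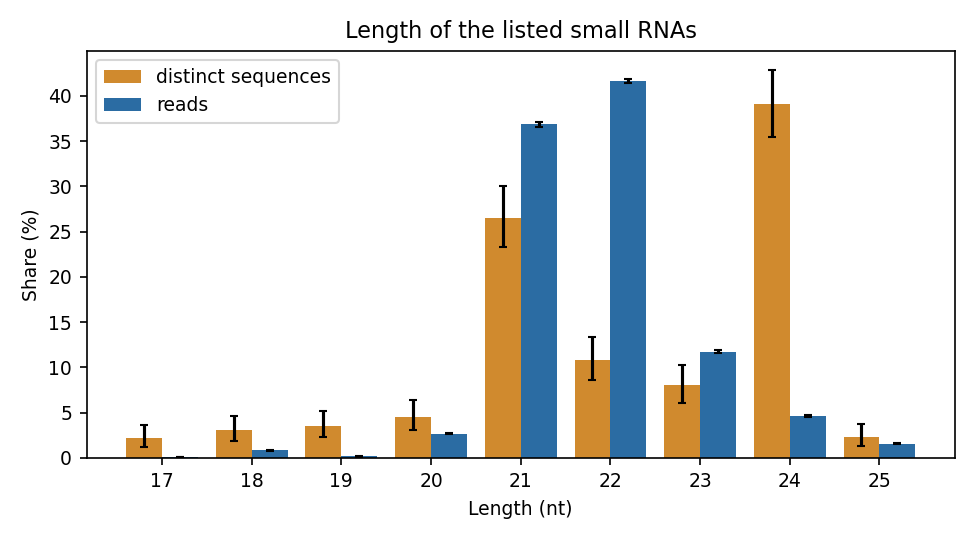
Length in nucleotides (horizontal axis) against the share (%) of the 686 distinct small RNA sequences and of their 135737 reads, with exact 95% intervals as error bars. Distinct sequences peak at 24 nt (39.1%) and reads at 22 nt (41.6%).

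The next question was which predicted targets showed cleavage in the degradome. Of the 18764 predicted pairs, 1010 were detected (5.38%, 5.06 to 5.72%), on 666 transcripts and by 198 small RNAs. The authors sorted each detected pair into a category from 0 to 4, which by convention runs from the highest signal on the transcript to single reads. Category 0 held 119 pairs (11.8%, 9.86 to 13.9%) on 40 transcripts, with a median of 16 raw reads at the site. Category 1 held 9 pairs on 4 transcripts, category 2 held 331 pairs (32.8%) and category 3 held 41 pairs. Category 4 held 510 pairs (50.5%, 47.4 to 53.6%), each with 1 raw read. Of the 124 pairs with an authors' p of at most 0.05, 115 were in category 0 and 8 in category 1. Several related small RNAs can point to the same position, and with each transcript and position counted 1 time, category 0 made up 4.85% of the sites.

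The transcripts with the most reads at a category 0 site encoded growth-regulating factors, a GRAS protein and auxin signalling proteins. GRF5 (Sme2.5_09470.1_g00002.1), one of the growth-regulating factors that promote cell proliferation in young organs, had 130 raw reads at nucleotide 704 of the transcript, at a miR396 site (alignment score 3, p = 0.0149 by the authors). SCL6 (Sme2.5_05903.1_g00003.1), a GRAS transcription factor of meristem maintenance, had 86 raw reads at nucleotide 1085 at a miR171 site (p = 0.00167 by the authors). GRF4 (Sme2.5_00676.1_g00016.1) had 85 raw reads at nucleotide 347, again for miR396. The ARF8 transcripts, which encode an auxin response factor of flower and fruit growth, had 79 raw reads at nucleotide 1184 of Sme2.5_06421.1_g00006.1 and 78 at nucleotide 2159 of Sme2.5_04886.1_g00002.1 for miR167. Their deposited normalized reads were 40 and 39, which, read as raw reads divided over the places they match, means that the reads were shared with other places. ARF18 (Sme2.5_03336.1_g00003.1) had 72 raw reads at nucleotide 1379 for miR160. The auxin receptor TIR1 had 61 raw reads for miR393 on each of Sme2.5_05303.1_g00001.1 (nucleotide 1609) and Sme2.5_01762.1_g00002.1 (nucleotide 1393), with 19.1 normalized reads on each. AP2 (Sme2.5_00029.1_g00014.1), a floral organ identity gene, had 48 raw reads at nucleotide 1435 for miR172, and the GAMYB transcript GAM1 (Sme2.5_04770.1_g00001.1) had 35 at nucleotide 961 for miR159.

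A comparison over families set the detected sites of each conserved miRNA on its textbook target family beside those of other small RNAs. Of 27 families with annotated sites, 18 passed (one-sided Fisher's exact test with Benjamini-Hochberg adjustment). Of the others, miR398, miR403, miR2118, miR5300 and miR530 had 0 predicted textbook transcripts and so could not pass. Among the 18, miR166 was found on homeobox-leucine zipper transcripts at 13 of its 17 annotated sites. Other small RNAs had 4 of 557 such sites (exact test, adjusted p = 1.45e-18). The 13 sites lay on 7 transcripts, with nucleotides 550, 551 and 552 of ATHB-15 as separate sites. Such neighbouring sites, also found for miR160, miR172, miR171, miR156 and miR394, are not independent, as the test assumes they are. Both annotated sites of miR394 lay on FBX6, at nucleotides 1165 and 1166. For miR172 and AP2-like transcripts the counts were 7 of 17 against 0 of 557 (exact test, adjusted p = 6.69e-11), and for miR160 and auxin response factors 5 of 8 against 3 of 566 (adjusted p = 3.28e-08). For miR156 and SPL transcripts they were 4 of 7 against 0 of 567 (exact test, adjusted p = 3.52e-08). The miR396 family was found on growth-regulating factors at 9 of 100 sites against 0 of 474 (exact test, adjusted p = 3.93e-07; 9.03e-15 without repetitive small RNAs), and miR171 on GRAS transcripts at 3 of 5 against 0 of 569 (adjusted p = 9.57e-07). The other families that passed were miR159, miR162, miR164, miR167, miR168, miR169, miR319, miR393, miR394, miR858, miR6024 and miR6027. This test holds the target prediction as well as the degradome, since 16 of the 18 families also passed it on all predicted pairs, without any degradome read. A test within each family, added after the data were seen, compared detection of predicted textbook targets with that of its other predicted annotated transcripts. Of the 18, 9 passed (one-sided Fisher's exact test, adjusted over 22 families): miR396, miR172, miR166, miR159, miR319, miR156, miR393, miR167 and miR394. Transcripts with shared reads counted as separate detections here. Every textbook site of miR393 and miR167 had shared reads, as had all those of miR166 except ATHB-14. Another 7 of the 18 (miR160, miR162, miR164, miR168, miR169, miR171 and miR6027) had the smallest p that their totals of predicted and detected transcripts allow. These totals already contain the outcome, such as 9 of 71 other transcripts detected for miR169 and 2 of 3 textbook targets for miR164. For these 7 the test decides neither for nor against detection. Growth-regulating factors of miR396 were detected in 9 of 10 cases against 78 of 390 other transcripts (exact test, adjusted p = 0.00014), and AP2-like transcripts of miR172 in 5 of 6 against 10 of 170 (exact test, adjusted p = 0.000142). For miR160 the detected targets were 4 of 4 against 3 of 10 (exact test, adjusted p = 0.0769). The other families were miR6024 with 7 of 19 against 2 of 7 (exact test, adjusted p = 0.696) and miR858 with 2 of 8, both single reads, against 1 of 4 (exact test, adjusted p = 0.884, smallest p allowed 0.255 before adjustment). In the first test with only sites whose reads matched 1 place, 13 families passed: miR166 did not pass the exact test (adjusted p = 0.0924), miR6024 had no textbook site left, and miR167, miR393 and miR6027 had no annotated site left. Calls of the exact test also ended for miR159 with only sites of authors' p at most 0.05 (adjusted p = 0.110) and with 1 vote per target annotation (adjusted p = 0.189), for miR169 without repetitive small RNAs (adjusted p = 0.0568) and for miR6027 in categories 0 to 2 (adjusted p = 0.0533). At scores of 2.5 or less miR396 and miR6024 had no textbook site left, as their best textbook scores were 3 and 3.5. Further called families had no annotated site left and could not be tested: miR167, miR168, miR169 and miR6027 at scores of 2.5 or less, miR156, miR164, miR168, miR169, miR6027 and miR858 with the authors' p at most 0.05, and miR858 in categories 0 to 2.

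Detected textbook targets differed widely in read number between families. All 7 predicted homeobox-leucine zipper transcripts of miR166 were detected, including ATHB-8 with 14 raw reads, ATHB-14 with 8 and HOX10 with 5, all in category 0. ATHB-8 had 4.67 normalized reads and HOX10 had 1.25, so the reads of both were shared with other places. A further member carried the symbol AGO4A although its annotation was homeobox-leucine zipper. All 4 ARF transcripts of miR160 were in category 0, as were 4 of the 5 detected AP2-like transcripts of miR172 and 4 of the 9 detected growth-regulating factors of miR396. DCL1 (Sme2.5_02774.1_g00001.1), the Dicer that processes miRNAs, had 20 raw reads at nucleotide 3111 for miR162 (p = 0.0013 by the authors), and the F-box transcript FBX6 had 6 at nucleotide 1166 for miR394. The TCP3 transcripts had 4 raw reads (nucleotide 1244, category 0) and 2 raw reads (nucleotide 695, category 1) for miR319. AGO1B, an Argonaute of the miRNA pathway, had 8 raw reads for miR168 in category 2 (p = 0.089 by the authors). NFYA1 of miR169 had 3 raw reads, while SPL9 of miR156 and NAC021 of miR164 had 2 each, all in category 2, and MYB12 of miR858 had 1.

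Several families had little or no degradome signal on their textbook targets. The miR482 family, first in reads, had 15 predicted NBS-LRR transcripts, of which 2 were detected, and it did not pass the test (exact test, adjusted p = 0.257). The best of them carried the symbol N, a virus resistance gene of tobacco, with 3 raw reads in category 0. Textbook words match only transcripts with an annotation or symbol, here these 15 and 694 others of 1665 predicted for miR482. The unannotated Sme2.5_03824.1_g00004.1 had 6 raw reads in category 0 for miR482 at nucleotide 253 (p = 0.0116 by the authors), a position also predicted for miR5301. Whether unannotated transcripts encode NBS-LRR proteins could not be told. Of the 13 laccase transcripts predicted for miR397 (78 reads), at alignment scores down to 1.5, 0 were detected, as were 0 of 2 for miR408 (832 reads), 0 of 1 for miR6022 (154 reads) and 0 of 3 for miR6026 (33 reads). Transcript levels were not measured, so absence of reads does not show that these sites are uncut. For miR6024, 7 of 19 predicted resistance transcripts were detected, but R1B-17, RPP8L4 and RPM1 each had 5 raw reads and 0.714 normalized reads, so these reads cannot be assigned to 1 gene. RPP13L3 had 2 raw reads and 0.2 normalized reads for miR6027.

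**Figure D3:**
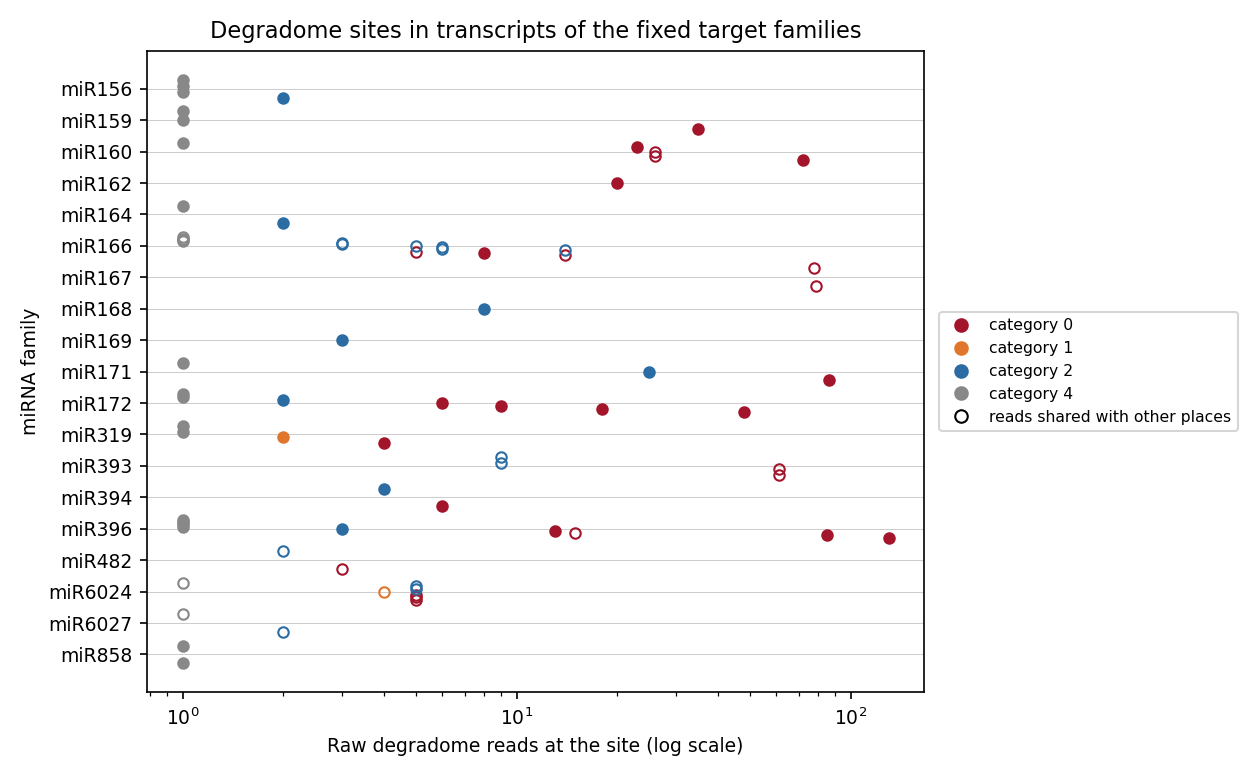
Raw degradome reads (log scale, horizontal axis) at each detected site on a textbook target transcript, by miRNA family, with 1 point per site, colour for the authors' category and open points for sites whose reads also matched other places. GRF5 of miR396 lies farthest right at 130 reads, and all 7 miR6024 points are open.

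Textbook targets were compared with all other detected transcripts in their category. Of the 62 textbook target transcripts detected, 30 were in category 0 or 1 (48.4%, 35.5 to 61.4%), among them GRF5, SCL6, ARF8, TIR1, AP2, GAM1 and DCL1. Of the 604 other transcripts, 14 were (2.32%, 1.27 to 3.86%). The odds ratio was 38.9 (18.0 to 87.9; two-sided Fisher's exact test, p = 2.60e-24). Detection itself also differed, in a comparison added after the data had been seen: 62 of 122 predicted pairs of a family and a textbook target transcript were detected (50.8%, 41.6 to 60.0%), against 165 of 2877 other annotated pairs of the same families (5.74%, 4.91 to 6.65%), with an odds ratio of 16.9 (11.3 to 25.5; Fisher's exact test, p = 7.23e-40). Neither this comparison of detection nor the test within each family was matched for alignment score or set retroelement transcripts apart. Their part in the difference was not tested. Members of a gene family are not independent, and 14 of the 30 textbook positions in category 0 or 1 had reads shared with other places.

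Grouped by function, auxin signalling and transcription factors of flower and meristem led the high categories. The lists share gene families with the textbook targets, and their transcripts in category 0 or 1 were all textbook targets. The list test thus regroups the comparison above and is no separate support for it. Of 12 detected auxin signalling transcripts, 8 were in category 0 or 1, led by ARF8, ARF18 and TIR1 (odds ratio 33.8, 8.57 to 161; two-sided Fisher's exact test, adjusted p = 2.73e-07). Reads were shared with other places in 6 of these 8, and with only sites whose reads match 1 place the adjusted p of the exact test was 0.0355 (odds ratio 32.8). Of 38 detected flower and meristem transcription factors, 14 were, led by GRF5, SCL6 and GRF4 (odds ratio 11.5, 4.99 to 26.1; Fisher's exact test, adjusted p = 7.91e-08). This odds ratio was 6.33 without repetitive small RNAs, and with all predicted transcripts as background it was 70.9, against 258 for auxin signalling. Of 13 disease resistance transcripts, 5 were (odds ratio 9.76, 2.40 to 35.7; Fisher's exact test, adjusted p = 0.00203), but 0 of them had reads that matched 1 place only, and with such sites alone the adjusted p was 1. Its odds ratio was 5.54 without repetitive small RNAs, 15.9 with all predicted transcripts as background and 19.1 with 1 vote per annotation. The small RNA machinery had 1 of 5, DCL1, in category 0 or 1 (Fisher's exact test, adjusted p = 0.508), with AGO1B in category 2.

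The remaining lists gave no transcript in category 0 or 1. Cysteine and methionine metabolism, a list taken from the series description and so no independent choice, had 0 of 10 (upper bound of the odds ratio 6.43, Fisher's exact test, adjusted p = 1), with PRY3 highest at 14 raw reads in category 2. Hormones of style length had 0 of 4 (Fisher's exact test, adjusted p = 1): CYP85A1 of brassinosteroid synthesis, EBF1 of ethylene signalling and DREB1A each had 1 raw read. Ribosomal proteins, histones, tubulins, actins and elongation factors, taken as a comparison list, had 0 of 22 (Fisher's exact test, adjusted p = 0.544), although RPL24 had 61 raw reads and RPL5 had 21, both in category 2. In self-incompatibility and ubiquitin 0 of 5 predicted transcripts were detected, and in nutrient and copper genes 0 of 23. Neither list could thus be tested among detected transcripts. With all predicted transcripts as background both had an odds ratio of 0, with upper bounds of 327 and 52.8. Bounds this wide decide nothing for either list.

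The final comparison linked both libraries. Of the 76 named families in the small RNA table, 71 had a predicted target, 46 had a detected one, and 16 had one in category 0 or 1. By name, 198 of the 686 small RNAs were found in a detected pair, 55 of them without a known family. Across the 71 families, reads and the number of detected transcripts had a Spearman rho of 0.259 (permutation test, p = 0.0297, adjusted p = 0.0593). The Pearson r was 0.208 on the log scale (permutation test, p = 0.0824, adjusted p = 0.0824), for 2 relations tested. Detected transcripts of any category were counted, single reads included, so not all of them need be cleaved targets. Without the 2 families farthest from the median, r was 0.129 (p = 0.294) and rho 0.205 (p = 0.0916), so the unadjusted call of rho rests on those families among all small RNAs. Without repetitive small RNAs, rho was 0.331 (p = 0.00529) and r 0.334 (p = 0.00486), and in categories 0 to 2 rho was 0.311 (p = 0.00837). Families are not independent replicates, and per small RNA name rho was -0.0092 (p = 0.877). The small RNAs with most detected transcripts were a miR6426b form (UUUUUUCUUCUUCUUCUUCU) with 150, a miR396c form (CUUCUUCUUCCUCUUCUUCCU) with 106, a pair of miR414 forms with 103 (UCAUCAUCAUCAUCGUCG) and 32 (CAUCAUCGUCAUCAUAAUCAUC), and a miR482a form (UGAUGAUGAUGAUGAGG) with 27, and none of these 5 had more than 2 reads in the small RNA library.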

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

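The alternatives without repetitive small RNAs, without names matching ribosomal or transfer RNA, without PC names, with reads that match 1 place, with all predicted transcripts as background and without the families farthest from the median, and the test of detection within each family, were chosen after the results were seen. With each distinct sequence counted 1 time, the shares of miR482, miR166 and miR2911 were 1.60%, 2.77% and 0.437%. The miR482 share was 27.2% with at least 10 reads per sequence and 35.1% without names matching ribosomal or transfer RNA, where miR166 had 20.3%. Without miR482 in the total, miR166 had 21.3% and miR2911 13.9%. These follow from the changed totals. Weighted by reads, 21, 22 and 24 nt held 36.8%, 41.6% and 4.58%. Of distinct sequences with a known family, they held 40.4%, 14.5% and 13.6%.

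Category 0 held 92.7% of pairs with an authors' p of at most 0.05, and categories 2 and 4 held 0%, since that p nearly fixes the category. With each position counted 1 time, category 0 held 4.85% and category 4 54.3%. With each transcript at its best category, category 0 held 6.01% and category 2 37.4%. Without repetitive small RNAs, they held 22.7% and 25.8%.

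With an authors' p of at most 0.05, 11 of the 12 called families with an annotated site left passed the textbook target test, 0 lists passed, 15 families had a detected target, and the odds ratios of categories were not finite (Fisher's exact test, p = 0.25 for textbook against other targets). That of auxin signalling was also not finite at alignment scores of 2.5 or less (exact test, adjusted p = 7.82e-07). Detection within each family was called for 9. The other alternatives gave 12 to 18 families, the lowest being 12 of 14 left at scores of 2.5 or less (the others had no textbook site left) and 13 of 15 left with reads that match 1 place, and the odds ratio of textbook against other targets lay between 24.6 and 282. The disease resistance list turned to an odds ratio of 0 with only sites whose reads match 1 place. By name, 198 small RNAs overlapped, a larger unit count than families. The relation of reads and transcripts turned to -0.0092 per name and fell to 0.205 without the 2 most abundant families. Leaving out the 2 families farthest from the median gave the same rho and r, so it is not a separate check. The relation was 0.311 in categories 0 to 2 and 0.331 without repetitive small RNAs, and the cause was not tested. An alignment limit of 4 removed no pair and tests nothing. The median detected pair had 1 raw read, and the effect of depth was not tested.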

Other observations

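All tests in this part were chosen after the results were seen. The 24 nt class had its own base preference: 168 of its 268 sequences began with A (62.7%, 56.6 to 68.5%, exact binomial test against 0.25, p = 1.11e-38), whereas 45 of 74 sequences of 22 nt began with U (60.8%, 48.8 to 72.0%, p = 7.59e-11). In plants, 24 nt small interfering RNAs that begin with A are typically bound by AGO4 and direct DNA methylation. Transcripts with retroelement symbols were the partner in 3106 predicted pairs of non-repetitive small RNAs outside the textbook targets, and 9 of these were detected (0.290%, 0.133 to 0.549%). Other annotated transcripts had 198 of 3366 (5.88%, 5.11 to 6.73%). Pooled over alignment scores, the Mantel-Haenszel odds ratio was 0.0536 (0.0279 to 0.103). Of the 9 detected retroelement pairs 0 were in category 0 or 1, against 11 of the 198 others. With 9 pairs this 0 decides nothing about category. Pairs on related transcripts are not independent here, and transcript levels were not measured.

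Some category 0 sites lay outside the textbook families. A transcript with the symbol NRPD2b, but annotated as subunit B of RNA polymerase II, had 15 raw reads in category 0 at nucleotide 443 for miR396 (p = 0.0039 by the authors), with 7.5 normalized reads. Those are also the raw and normalized numbers at GRF4 of Sme2.5_00130.1_g00023.1. PP2A13, a gene of the phloem protein 2 kind, had 5 raw reads in category 0 for miR482c (p = 0.00519 by the authors). A small RNA without a known family, PC-5p-513841_2, had a category 0 site with 18 raw reads at nucleotide 624 of Sme2.5_02708.1_g00010.1, a transcript without annotation (p = 0.00999 by the authors). A miR159 site on the unannotated Sme2.5_00589.1_g00012.1 had 14 raw reads at nucleotide 742. The textbook sites GAM1 (nucleotide 961) and TCP3 (nucleotide 695, 2 raw reads) were each predicted for both miR159 and miR319, so the degradome does not tell which miRNA cut there.

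Repetitive small RNAs held a large part of the detected pairs. The 14 sequences with few distinct 3 nt words, such as the miR6426b form and the miR414 forms, held 503 of the 1010 detected pairs (49.8%, 46.7 to 52.9%) with 29 reads among them. Abundant guides of cleavage are argued against, since the highest read number among the 14 was 4, equal to the median of all sequences. Counted as transcript positions, 5 of their 481 were in category 0 or 1 (1.04%, 0.338 to 2.41%). Textbook positions had 30 of 74 (40.5%, 29.3 to 52.6%) and other positions 11 of 274 (4.01%, 2.02 to 7.07%). GAM1 at nucleotide 961 and TCP3 at nucleotide 695 are in both of these last counts, through miR159 and miR319. A candidate explanation is that these sequences match repeats in many transcripts, where background RNA ends meet the predicted position. Apart from abundant guides, no biological explanation was tested.

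Names known to match ribosomal or transfer RNA held 23.2% of the listed reads (23.0 to 23.4%). Of their reads 33.0% were 21 or 22 nt long (32.4 to 33.5%), against 95.8% for the conserved families, and 34.9% began with U, against 94.3%. Their 1576 predicted pairs gave 35 detected ones, 0 in category 0 or 1. Positions that were neither repetitive nor textbook reached these categories in 11 of 274 cases (4.01%), so 0 of 35 decides nothing. The miR2916 p5 and p3 sequences overlap by 6 nt end to end, which arms of a hairpin would not do, and 11 miR6300 sequences shared 1 start with 8 lengths from 18 to 25 nt. The lengths, first bases and overlaps fit fragments of ribosomal and transfer RNA rather than Dicer products. Without a genome the sequences were not mapped, and no biological explanation was tested.

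Cysteine and methionine metabolism rested largely on 1 annotation. The pathway group described here is not the same as the list tested above. It had 54 predicted and 11 detected transcripts, against 49 and 10 in that list. Of 124 predicted pairs on 54 transcripts of this pathway, 101 pairs on 36 transcripts carried the annotation DNA (cytosine-5-)-methyltransferase, but the symbol was a DNA methyltransferase in 2 of the 36, and 13 had a symbol of the PERK receptor kinases. Repetitive small RNAs made 87 of the 124 pairs (70.2%) and 11 of the 13 detected ones. The lowest authors' p of a detected pair was 0.0699, for enolase-phosphatase E1 and miR398, and 0 of 5 ethylene synthesis transcripts were detected. An annotation carried over from unlike proteins is a candidate explanation for the size of this group, which the value of 2 symbols fits; symbols can be wrong too, and no biological explanation was tested.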
